A study of Mus musculus with 6 samples.

How the data were processed

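RNA sequencing measured gene expression in adult olfactory epithelium of NMRI mice that were wild type (WT) or lacked NKCC1 (KO), the sodium-potassium-chloride cotransporter encoded by Slc12a2. Each genotype had 3 pooled libraries. Per the labels' descriptions, the mixed pool held 2 olfactory epithelia of each sex, and the male and the female pool each held epithelia of 3 mice. Per the labels' protocols, RNA was isolated on columns with a DNase step, and the libraries were treated with duplex-specific nuclease before sequencing. That enzyme digests the abundant double strands that re-form first, so it lowers the most abundant transcripts relative to the rest and compresses their differences.

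The deposited table gives 1 FPKM value (fragments per kilobase of transcript, scaled to the fragments mapped in the library) per gene symbol and library. The unit is not written in the table. It was taken from the form of its header, from the values and from the programs named. Per the submitters' processing notes, these programs were TopHat2 2.0.7, Bowtie, Cufflinks 1.3.3 and Cuffdiff, with the mouse build mm9. Their settings, the gene annotation and any further scaling of the FPKM are not given in the sources used here. The male and female columns carry the sample titles in full. The 2 columns without a sex were assigned to the mixed pools, the only library left in each genotype. The reference at hand is of build GRCm38, so no coordinates are given.

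The table holds 22310 rows and 21881 distinct symbols. Of the 221 symbols on several rows, the row of highest mean was kept and 429 rows were left out, 7 of them with a mean of at least 0.5 FPKM. Genes with a mean of at least 0.5 FPKM over the 6 libraries were tested, which left 15067. Values were analysed as log2(FPKM + 1), so each log2 change is on that scale and understates the change of low genes. KO and WT were compared with limma 3.58.1 in R 4.3.3, with a prior variance that follows the mean, Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p for a gene comes from limma. The effect of sex was the coefficient of the female share of the pool (0, 50 or 100%) beside genotype, and its product with genotype tested whether the KO effect differed with sex. Summed FPKM were compared by two-sided exact permutation tests, whose smallest possible p is 0.1 with 3 libraries against 3. Each library is a pool of several animals, and the labels do not say whether any animal is in more than 1 pool. The p-values measure the spread between pools, not between single mice.

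Counts are not used here, and depth was estimated from the low values. The value of 1 fragment was read from genes with a single annotated transcript of at least 1200 nt, taking off 150 nt for fragment ends. The estimates were 3810000 fragments for the WT mixed, 14220000 for the WT male, 11160000 for the WT female, 3970000 for the KO mixed, 13270000 for the KO male and 11550000 for the KO female library. For a gene of 1 kb, 1 fragment is then worth 0.26 FPKM in the WT mixed library and 0.070 in the WT male library. The lengths come from GRCm38 models, so these depths are approximate. An exact 0 can be a failed estimate of the authors' program, and such genes are described as listed at 0.

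Before the data were examined, the groups, the tests, 34 gene lists and a rule for the genes to be named were fixed. The rule takes Slc12a2, the 12 largest changes in each direction among genes past the threshold whose 3 KO libraries all lie on one side of the 3 WT libraries, up to 4 members per list with a mean of at least 1 FPKM and the smallest p, up to 6 sex-dependent genes per direction with the sex-linked list, and up to 6 genes for the difference between sexes. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over the 34 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it. For each list, members were also counted with p-values adjusted over the list alone. Most lists are marker genes of cell types of the nose, and members of a list can also be expressed by other cells of the epithelium.

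The tests were tried on simulated data with the variance of the real genes. In 10 runs over 15067 genes with 200 changed genes, the genotype test recovered 15.3% of genes changed by log2 1 and 80.1% of genes changed by log2 2, and 4.70% of its calls were false. The simulated errors were normal and independent between genes, and only genes with a mean log2(FPKM + 1) above 1 were changed. Genes of the real data vary together, so these rates need not hold there. Alternatives covered the pseudocount, the filter, the scaling, the prior variance, each library left out in turn, the mixed pools left out, terms for the kind of pool and for sex, and other list tests. A term for the shallower mixed pools, a secretory covariate and the removal of small RNA genes were added after the data were seen. Figures were drawn with matplotlib 3.10.9.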

Results

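Transcripts of the olfactory epithelium, the sensory lining of the nose, were measured in 3 WT and 3 KO libraries. In each genotype 1 pool was of mixed sex, 1 male and 1 female. The mixed pools were shallower, at an estimated 3810000 (WT) and 3970000 (KO) fragments, than the male and female pools, at 11160000 to 14220000 fragments. Correlations of log2 expression between libraries ran from 0.94 to 0.98 within a genotype and from 0.93 to 0.97 between genotypes. The 10 most abundant genes held 15.5, 16.4 and 45.7% of the summed FPKM in the WT mixed, male and female libraries and 33.5, 34.4 and 16.9% in the KO ones. The series title names the modulation of neurogenesis by NKCC1 as its subject, and the comparison of KO with WT asks which transcripts differ when the transporter is missing.

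Slc12a2, the targeted gene, which encodes the cotransporter that loads olfactory neurons with chloride, was lower in each KO library than in each WT library. Its FPKM was 53.2 ± 26.2 in WT and 20.7 ± 6.42 in KO (SD, n = 3 each). The KO level was 33.7% of the WT level in the mixed, 39.98% in the male and 50.03% in the female pools. The change of -1.26 ± 0.32 (SE) on the log2 scale had an adjusted p of 0.11 in limma, which did not pass, and the exact permutation p was 0.1, the smallest possible. With a term for the mixed pools the adjusted p was 0.0089, and without the WT female library it was 0.0050. FPKM per gene do not tell whether the remaining fragments come from a changed transcript.

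Of the 15067 genes tested, 32 rose and 94 fell in KO, and in all 126 the KO and WT libraries did not overlap. Such separation was found for 12.7% of all tested genes, where chance gives 10%. Of the 94 that fell, 80 were odorant receptors. At an unadjusted p under 0.05, 642 genes were higher and 696 lower, where 753 in all would be met by chance.

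The largest rise was that of Chi3l4, a chitinase-like protein, from 54.2 ± 86.4 to 6168 ± 1681 FPKM (log2 change 8.59 ± 0.97 SE, adjusted p = 0.0013, n = 3 each). Among the WT libraries, the male pool held 154 FPKM of Chi3l4 and the other 2 held 2.34 and 6.31. Fcgbp, a mucus protein of secretory epithelia, rose from 1.49 ± 0.66 to 57.8 ± 15.2 FPKM (adjusted p = 7.5e-06), the smallest adjusted p of all genes. Retnla, a secreted resistin-like protein, rose from 0.12 ± 0.11 to 11.4 ± 4.65 FPKM and was listed at 0 in the WT mixed library. Alox12e, a lipoxygenase, rose by 3.48 ± 0.33 and Sprr1a, a protein of squamous epithelium, by 3.98 ± 0.52 on the log2 scale. The eosinophil-associated ribonucleases Ear10, Ear2 and Ear1 rose by 2.69, 2.47 and 2.43 (adjusted p = 0.049, 0.0018 and 0.015), Ear10 only narrowly past the threshold. Igj, the joining chain of secreted immunoglobulin, rose from 45.4 ± 25.4 to 233 ± 117 FPKM, and Wfdc3 rose by 2.18. Clca2, of the family of calcium-activated chloride channel regulators, rose by 2.70 ± 0.50 (adjusted p = 0.025), with 4.68 FPKM in the WT male pool and 7.40 in the KO male pool.

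Further genes that rose, singled out after their values were seen, were Ccl11, an eosinophil chemoattractant, from 0.40 ± 0.19 to 5.19 ± 1.11 FPKM, and Il13ra2, a receptor for interleukin 13, from 0.18 ± 0.035 to 2.77 ± 0.69. Pigr, which carries immunoglobulin across epithelia, rose from 78.8 ± 53.1 to 296 ± 95.7 FPKM, and complement C3 from 4.55 ± 3.28 to 17.1 ± 3.06. Amd1, which was named by the rule set beforehand, rose from 0.60 ± 0.44 to 26.3 ± 4.67 FPKM. Amd2, a near-identical copy singled out afterwards, fell from 43.6 ± 6.20 to 15.2 ± 4.14. Fragments can be shared between such copies, so these 2 values, and those of the Ear and chitinase-like families, are uncertain gene by gene.

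**Figure D1:**
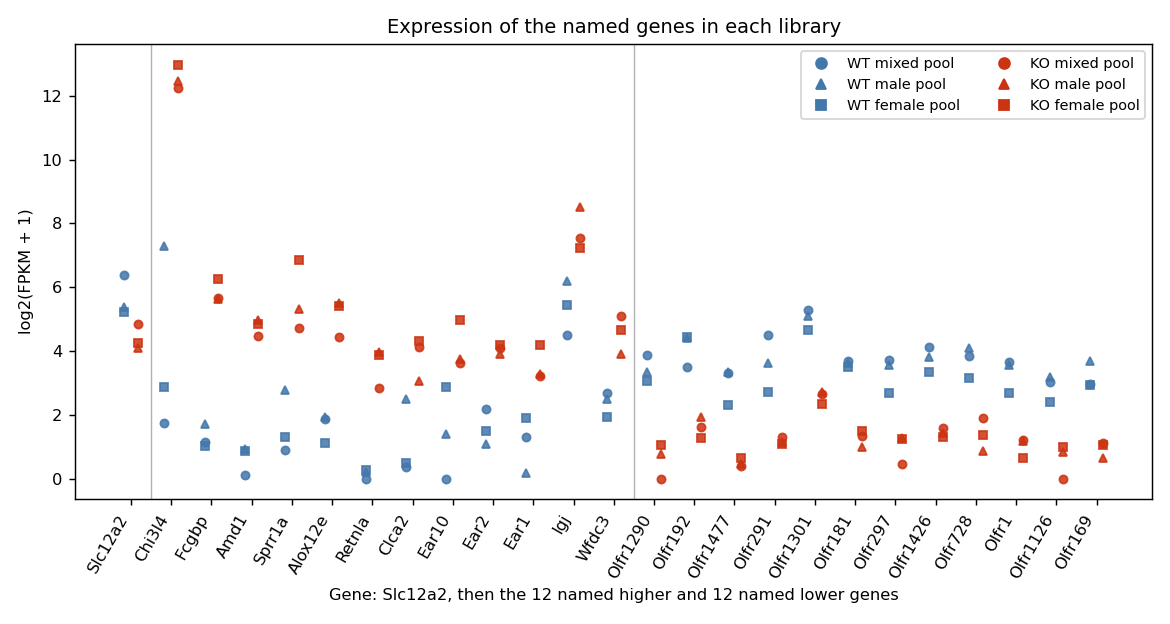
Expression on the log2(FPKM + 1) axis of Slc12a2, the 12 named genes that rose and the 12 that fell, with 1 point per library (blue WT, red KO; circle mixed, triangle male, square female pool). In each of these genes the 3 KO points lie on one side of the 3 WT points.

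Odorant receptors, the G protein-coupled receptors of which each olfactory neuron uses mostly a single gene, made up the bulk of the genes that fell. Of 891 tested, 80 fell and 0 rose over all genes tested, and 290 fell and 3 rose when adjusted over the list alone. The receptors were taken by symbol, so they include pseudogenes, such as Olfr1372-ps1 and Olfr391-ps among the 80. The odds of a receptor being among the genes that fell were 99.7 times those of other genes (Fisher's exact test, p = 1.4e-84, across genes, which are not independent). Olfr1290 fell from 10.03 ± 3.28 to 0.59 ± 0.54 FPKM (log2 change -2.82 ± 0.32 SE, adjusted p = 0.0013, n = 3 each) and Olfr1301, the most abundant of the 12 named, from 31.8 ± 6.92 to 5.01 ± 0.81. The other 10 named, Olfr192, Olfr1477, Olfr291, Olfr181, Olfr297, Olfr1426, Olfr728, Olfr1, Olfr1126 and Olfr169, fell by log2 changes of -2.51 to -2.25. The median receptor changed by -0.54, 738 of 891 had a negative and 153 a positive change, and the fifth percentile was -1.57. Copies of the receptor family resemble each other, so values of single receptors are uncertain. The summed FPKM of all receptors was 3514 ± 887 in WT and 1921 ± 349 in KO (exact permutation p = 0.1, the smallest possible).

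Mature olfactory neuron genes were also lower in KO. All 20 tested members of that list had a negative change, with a median of -0.74. Kirrel2, an adhesion protein of olfactory axons, fell from 279 ± 108 to 79.0 ± 35.2 FPKM (adjusted p = 0.035), the only member to pass over all genes, and 9 fell when adjusted over the list alone. Among these were S100a5 (-1.36 ± 0.34), Rtp2 (-0.91 ± 0.25), a receptor transport protein, and Cnga4 (-1.03 ± 0.28), a subunit of the odour transduction channel. The summed FPKM of the list was 11723 ± 2761 in WT and 6032 ± 1242 in KO (exact permutation p = 0.1). By kind of pool, the KO sum was 38.7% of WT in the mixed, 41.2% in the male and 87.4% in the female pools, and for the receptors 41.1, 45.8 and 90.1%. The median FPKM of genes above 0 also moved with the kind of pool. It was 7.79, 5.87 and 4.21 in the WT and 6.53, 4.94 and 6.43 in the KO mixed, male and female libraries. The percentages of both lists therefore hold a shift between pools shared by many genes. Both lists passed camera at the preset correlation (adjusted p = 8.6e-49 for receptors and 8.9e-14 for mature neurons), and neither passed with an estimated correlation (adjusted p = 0.45 and 0.46). Among the 4 male and female libraries alone, the medians were -0.36 for receptors and -0.53 for mature neuron genes. The mixed pools alone, 1 against 1, allow no test.

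Genes of immature olfactory neurons, of neuronal progenitors and of dividing cells did not pass. None of the 15 immature, 10 progenitor and 27 proliferation genes was called, at an unadjusted p under 0.05 none either, and the list medians were -0.02, 0.17 and 0.16 (camera adjusted p = 0.99, 0.14 and 0.12). The immature list had a mean of 0.02 against its median of -0.02. Stmn2 was at 96.4 ± 16.98 FPKM in WT and 75.1 ± 13.8 in KO, Gng8 at 14.4 ± 4.46 and 18.5 ± 3.68, and Neurog1 at 2.62 ± 1.33 and 3.04 ± 0.70. For Gng8, the 95% interval of the log2 change was -0.23 to 0.96. The 12 apoptosis genes had a median of 0.03 (adjusted p = 0.59). The KO sum of FPKM was 66.1, 81.6 and 167% of WT in the mixed, male and female pools for the immature list and 73.3, 101 and 208% for the progenitors. Lists of other functions differed alike, at 79.0, 82.1 and 167% for the kinases of chloride cotransport and 78.0, 78.7 and 171% for the anion exchangers. Ribosomal sums did not, at 99.3, 99.7 and 99.4%. So this difference between pools is not particular to neurons. With each library left out the medians of the immature and progenitor lists ran from -0.31 to 0.19 and from -0.08 to 0.46. Without the WT mixed library the progenitor list passed at the preset correlation, higher in KO (median 0.46, adjusted p = 0.0066), as it did without both mixed pools (0.49, 0.029). The proliferation list passed too at the preset correlation without the WT mixed library (0.32, 0.045). The correlations estimated from all 6 libraries were far above the preset 0.01, at 0.81 for progenitors and 0.63 for proliferation, and with them the lists had an adjusted p of 0.82 and 0.84.

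**Figure D2:**
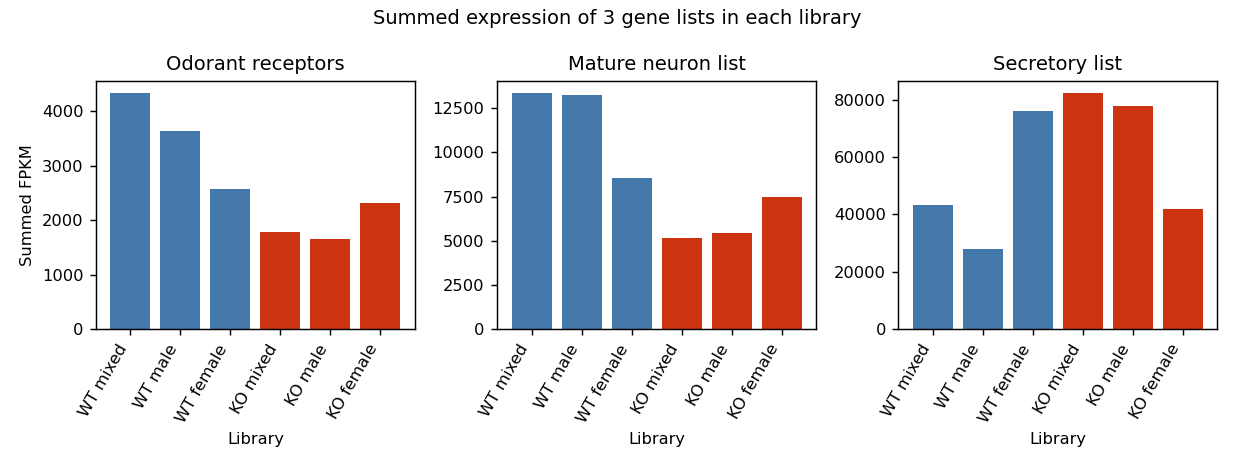
Summed FPKM of the odorant receptors, the mature neuron list and the secretory list in each library (bars from 0; blue WT, red KO). Receptor sums lay between 1664 and 2318 in the KO libraries and between 2574 and 4336 in the WT libraries, while the secretory sums of the genotypes overlapped.

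The other 14 genes that fell included Taar7b, a trace amine-associated receptor, Calb1, the calcium-binding calbindin, Kcnmb3, a potassium channel subunit, and Dlg2, a scaffold protein of synapses. Calb1 was at 5.98 ± 0.63 FPKM in WT and 1.40 ± 1.43 in KO and Kcnmb3 at 66.3 ± 22.0 and 18.9 ± 4.83. These were singled out after their values were seen, except Taar7b. Of the 11 trace amine-associated receptors tested, Taar7b fell over all genes (-1.39 ± 0.25, adjusted p = 0.023), Taar6 fell when adjusted over the list alone (-1.16 ± 0.33), and the list did not pass (adjusted p = 0.069).

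Lists of several non-neuronal cell types were higher in KO at the preset correlation. Macrophage and antigen-presenting genes had a median of 0.65 with all 14 positive and 7 higher when adjusted over the list alone, among them C1qc (16.5 ± 3.86 to 31.7 ± 7.53 FPKM) and H2-Aa (36.3 ± 19.3 to 73.6 ± 30.9). B and plasma cell genes had a median of 0.70, with Igj, 2010001M09Rik and Pou2af1 higher over the list alone. Of the bone and cartilage genes (median 0.58), Bglap and Bglap2 were higher over the list alone, and of the fibroblast genes (0.41), Col1a1 and Col1a2. Of the microvillar and ionocyte-like list (0.48), 3 genes were higher over the list alone, Trpm5 (2.65 ± 0.80 to 8.38 ± 3.15), Avil (1.52 ± 0.64 to 4.71 ± 1.19) and Gnat3 (0.28 ± 0.24 to 1.52 ± 1.01), the last outside the rule for named genes, while the list's summed FPKM in KO was 96.8% of WT (79.9, 83.6 and 131% in the mixed, male and female pools). Of the gland and secretory genes (0.48), the mucins Muc5b (19.8 ± 9.72 to 50.4 ± 15.7) and Muc5ac (1.26 ± 0.999 to 3.56 ± 0.55) were. With each library left out the medians ran from 0.43 to 1.09 for the secretory and from 0.21 to 0.54 for the fibroblast list. Endothelial genes (0.43), horizontal basal cell genes (0.65, with Krt5 at 28.9 ± 8.96 and 51.4 ± 15.5) and multiciliated cell genes (0.39) had no such member. The multiciliated call ended without the WT mixed library (median 0.39, adjusted p = 0.058), without the KO female library (0.23, 0.086) and without both mixed pools (0.42, 0.073), and the endothelial call without both mixed pools (0.30, 0.26). Of the immediate early genes (0.44), Atf3 was higher over the list alone. None of these 10 lists passed with an estimated correlation, where adjusted p ran from 0.45 to 0.64.

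Lower at the preset correlation, besides the receptors and mature neurons, were the erythroid (median -0.58), neutrophil (-0.41), brain glia (-0.37), sustentacular (-0.21) and oxidative phosphorylation (-0.08) lists. None of these 5 had a member that fell when adjusted over the list alone, and none passed with an estimated correlation (adjusted p = 0.53, 0.64, 0.45, 0.68 and 0.84). Hbb-b1, an erythroid gene, was at 208 ± 187 FPKM in WT and 63.8 ± 17.4 in KO. The erythroid result depends on the WT male library. The list's FPKM summed to 484, 2521 and 354 in the WT mixed, male and female libraries and to 410, 451 and 496 in the KO ones, and without the WT male library its median was -0.16 (adjusted p = 0.46). In the neutrophil list Ltf, which glands also express, went the other way and was higher over the list alone (176 ± 85.7 to 465 ± 133), and the list's summed FPKM in KO was 138% of WT. The neutrophil call ended without the WT male, the KO male or the KO female library, with medians from -0.83 to -0.17 over each library left out, and the brain glia call without the WT female or the KO female library. With list members of at least 2 FPKM neither passed (neutrophil median -0.39, adjusted p = 0.38, and brain glia median -0.0064, adjusted p = 0.46). Aldh1a7 of the sustentacular list was at 69.7 ± 13.5 and 42.4 ± 13.8. Lists that did not pass were olfactory ensheathing cells (-0.14, adjusted p = 0.28), vomeronasal neurons (0.27, 0.24), skeletal muscle (-0.04, 0.37), interferon response (0.20, 0.12), ribosomal proteins (-0.01, 0.95) and sex-linked genes (-0.21, 0.66). The ribosomal list had a mean of 0.01 against its negative median.

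**Figure D3:**
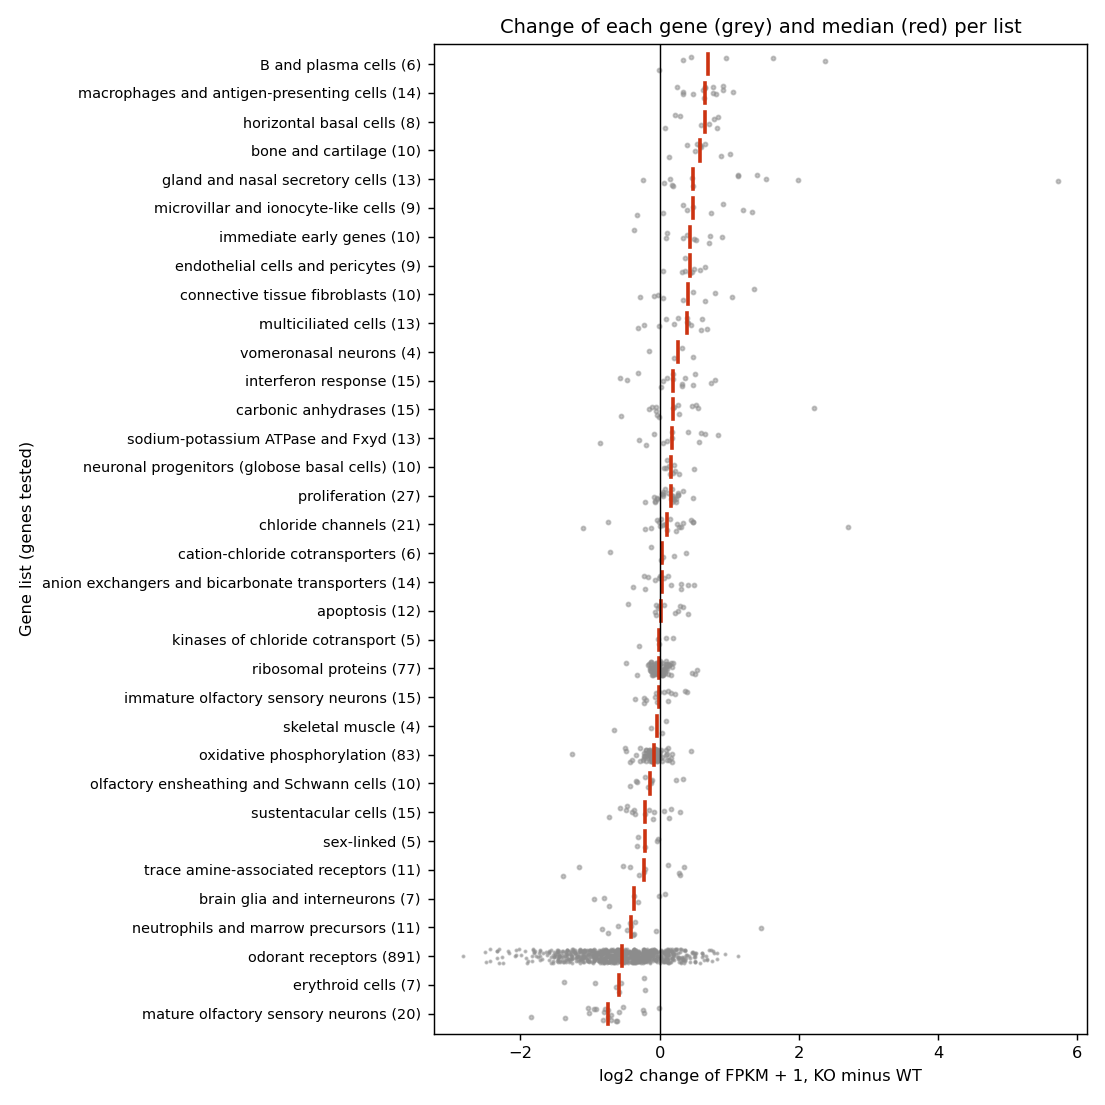
Change of each tested gene of the 34 lists on the log2 axis of FPKM + 1, KO minus WT (grey points, number of genes in brackets), with each list's median in red. Mature neuron genes lie lowest with a median of -0.74 and B and plasma cell genes highest with 0.70.

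Among other genes of chloride transport, 1 passed, the Clca2 named above. Of the 6 other cation-chloride cotransporters tested, 0 passed over all genes or over the list alone, and 1 had an unadjusted p under 0.05, Slc12a5, at 1.83 ± 0.93 FPKM in WT and 0.68 ± 0.07 in KO. Slc12a1 and Slc12a3 were below the filter, with means of 0.037 and 0.058 FPKM. None of the 14 anion exchangers and bicarbonate transporters passed or had an unadjusted p under 0.05, and Slc4a2 was at 17.4 ± 5.74 and 22.6 ± 2.74 (interval -0.18 to 1.002). Among the 21 chloride channel genes Ano2, the calcium-activated chloride channel of olfactory cilia, was at 70.0 ± 23.9 in WT and 40.04 ± 7.17 in KO (log2 change -0.74 ± 0.28, adjusted p = 0.37). No member of the kinases of chloride cotransport, the sodium-potassium ATPase and Fxyd genes or the carbonic anhydrases passed, and 0, 4 and 3 of them had an unadjusted p under 0.05. The camera adjusted p of these 6 lists were 0.87, 0.66, 0.18, 0.96, 0.14 and 0.14. The cotransporter list had a median of 0.04 and a mean of -0.03.

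The number of changed genes moved with the libraries used. It was 433 without the WT mixed, 81 without the WT male and 542 without the WT female library. Without the KO mixed, male and female libraries it was 44, 105 and 40. Receptor calls among the genes that fell were then, in the same order, 185, 36, 268, 23, 54 and 19. The 4 male and female libraries alone gave 348, 150 higher and 198 lower. A covariate for the secretory sum, which was 43339, 28093 and 76181 FPKM in the WT mixed, male and female and 82354, 77866 and 42007 in the KO libraries, left 43 higher and 18 lower, 16 of these receptors. The receptor median was then -0.44 against 0.15 for all genes, a gap of -0.59 where it was -0.55 without the covariate. The mature neuron median was -0.47 where it was -0.74 without the covariate, and 0 of its members passed in place of 1. With the covariate 3 residual degrees of freedom were left in place of 4.

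The comparison of sexes gave 5 genes higher and 10 lower with the female share, 5 of these 15 from the list of sex-linked genes. Xist, the RNA that silences an X chromosome, was at 25.7 and 30.6 FPKM in the WT and KO female pools and at 0.043 and 0.029 in the male pools (log2 change 4.81 ± 0.70 SE, adjusted p = 2.0e-04). In the WT and KO mixed pools Xist was at 42.2 and 33.1 FPKM, above the female pool of the same genotype, so it did not follow the female share. The Y-linked Eif2s3y, Ddx3y and Uty were listed at 0 in both female pools, and in the mixed pools lay below the male pool of the same genotype. They averaged 22.5, 8.17 and 5.26 FPKM in the male pools. Kdm5d averaged 2.93 in the male and 0.0078 in the female pools. Itln1, a lectin of mucus cells, averaged 4.199 FPKM in the male and 145 in the female pools, with 4.64 in the WT female and 285 in the KO female pool. Lcn4, a lipocalin, averaged 1832 in the male and 149 in the female pools, and Hbb-b2 was also lower. BC002163 and Gdpd3 were higher with the female share. Snord22, Snora34 and Snora47 are small RNA genes listed at 0 in several libraries. At an unadjusted p under 0.05 there were 112 genes. With quantile normalization, median-ratio scaling or no filter 0 genes passed in limma (152, 138 and 123 unadjusted), as without the KO female library (133), and without the WT female library 1 passed.

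The KO effect differed with the sex of the pool for 19 genes, 8 with a higher and 11 with a lower effect in females. Lcn2, an iron-scavenging lipocalin, was lower in the KO than in the WT male pool (138 against 257 FPKM) and higher in the KO than in the WT female pool (385 against 10.6). Mup6, a major urinary protein gene, and 2310057J18Rik went the opposite way. At an unadjusted p under 0.05, 562 genes had a higher and 64 a lower effect in females, 626 in all where 753 would be met by chance, and the median of all genes was 0.71. This test has 2 residual degrees of freedom and 10 of the 19 are small RNA genes, most of them listed at 0 in all but 1 or 2 libraries. With quantile normalization, median-ratio scaling or no filter 0 genes passed in limma, with 168, 144 and 392 at an unadjusted p under 0.05.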

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

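The 19 genes whose KO effect differed with the sex of the pool stand out because the test of the difference itself passed, 8 with a higher and 11 with a lower KO effect in females. The effect in females minus that in males was 5.95 ± 0.66 (SE) on the log2 scale for Lcn2, -5.09 ± 0.81 for the urinary protein gene Mup6 and -5.02 ± 0.82 for 2310057J18Rik. For small RNA genes it was 11.4 for Mir760, -7.89 for Snora64 and -9.76 for Snora33. Mir760 was listed at 0 in all libraries but the WT male (46.3 FPKM) and the KO female (54.8), and Snora33 in all but the WT female (868). Hba-a1, Wfdc12, Dnase1, Serpina3g, 5430402E10Rik and Gm5938 were also among the 19. The estimate for each sex rests on 1 pure pool per genotype, so a difference between sexes cannot be separated here from a difference between single pools.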

How the results depend on the processing

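Apart from terms for the mixed pools and the secretory sum and the removal of small RNA genes, these alternatives were set before the data were examined. Directions mostly held while counts did not, and the cause was not tested unless stated. Across genes and lists named singly, 1213 results under an alternative kept their side of the threshold, 227 lost the call and 9 gained one. Another 5 reversed, which was counted only where the main or the alternative result was called. For lists, direction was that against the other genes. Uncalled results that changed direction are among the 1213. The median of the uncalled immature list, for example, ran from -0.31 to 0.19 with each library left out. Genes that rose and fell numbered 12 and 18 with no filter, 93 and 177 with quantile normalization, 82 and 186 with median-ratio scaling, 67 and 142 with the female share as a covariate, 150 and 198 without both mixed pools, 88 and 201 with the term for the mixed pools, and 62 and 144 at an adjusted p of 0.1. The secretory covariate left 18 that fell, and removing the receptor genes left 7, of fewer genes tested. Leaving out each library in turn gave 15 to 184 that rose and 25 to 453 that fell.

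Slc12a2 was lower throughout, with an adjusted p from 0.0050 to 0.36. It passed with the female share (log2 change -1.26, adjusted p = 0.043), with the term for the mixed pools (-1.26, 0.0089) and without the WT female library (0.0050). With each library left out it ran from -1.49 to -0.89. A block for the kind of pool gave 150 genes that rose and 290 that fell, an adjusted p of 0.0082 for Slc12a2 (-1.26) and 4 lower lists. The kinds pair the pools only in part, the mixed pools best and the female pools not. The correlations of deviations from the genotype means were 0.36 for the mixed, 0.21 for the male and -0.09 for the female pools, and the WT female pool correlated best with the KO male pool (0.31).

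Of the lists, 10 were higher and 7 lower. Both counts were 0 with an estimated correlation and 0 with fry. Lower lists numbered 3 with quantile normalization and 4 with median-ratio scaling, and with each library left out 3 to 9, against 9 to 11 higher. The oxidative phosphorylation list turned in sign without the KO mixed library (0.052). Without the WT female library its median stayed negative (-0.10), and turned only against the other genes, which were lower still. The ribosomal list turned in sign in both cases (0.14 and 0.093). With each library left out the medians of the oxidative phosphorylation and ribosomal lists ran from -0.245 to 0.052 and from -0.137 to 0.14. The erythroid call ended without the WT male (-0.16, adjusted p = 0.46) and without the KO female library (-0.55, 0.22), and the sustentacular call ended in 4 of the 6 cases.

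Genes that differed with sex, 5 higher and 10 lower, numbered 0 and 0 with no filter, quantile normalization or median-ratio scaling, 10 and 18 at a mean of at least 2 FPKM, and 16 and 20 in male against female pools. With each library left out they ran from 0 to 19 and from 0 to 31. Genes whose KO effect differed with sex, 8 and 11, numbered 5 and 7 with a pseudocount of 0.1, 3 and 3 with a pseudocount of 5, 0 and 0 with no filter, quantile normalization or median-ratio scaling, and 16 and 27 at a mean of at least 2 FPKM. With a constant prior variance 5 were higher. With each library left out they ran from 7 to 2817 and from 5 to 91, so this count rests on single libraries. The effect of Snora33 ran from -19.5 to 0, and was 0 without the WT female library, the only one in which it is listed above 0.

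Depth limits the low genes, since 3 fragments of a gene of 1 kb are worth 0.79 FPKM in the WT mixed and 0.21 in the WT male library.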

Other observations

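The tests of the secretory sums, the secretory covariate, the olfactory tissue share, the shortened type 2 list and the macrophage comparison were chosen after the results were seen. Those of the receptors and of Pcp4l1 and Lrrc3b were written before the values they measure were seen, although each pattern had already been noticed. The tests of chance and of ciliated tissue for the type 2 list, of the olfactory tissue share and of the secretory sums were too lenient. They counted too much as evidence against a cause, and are read here more strictly than written. A list of further genes of the type 2 immune response, the reaction led by interleukins 4 and 13, was written after Chi3l4, Retnla and the Ear genes had been seen to rise, without any of the 30 smallest p. The list held 32 genes, of which 18 passed the filter on mean FPKM and were tested. The others fell below the filter, so the counts given here do not cover them. Of the 18 tested genes 17 had a positive change, 3 rose over all genes (Ear11, Chi3l3 and Ear1) and 9 when adjusted over the list alone. Ear1 is itself 1 of the rises already seen, and Ear11 and Chi3l3 are close copies of such genes, so these 3 add no new evidence. Without them 14 of 15 genes had a positive change, 0 rose over all genes and 6 when adjusted over the shortened list alone, Ccl24, Alox15, Ccl17, Ccl8, Arg1 and Socs1. Ccl24 went from 0.13 ± 0.12 to 1.05 ± 0.10 FPKM and Alox15 from 23.5 ± 6.10 to 56.8 ± 21.5 (SD, n = 3 each). Il33 was the exception, at 88.9 ± 7.49 in WT and 65.9 ± 25.6 in KO. Camera gave p = 2.3e-07 at the preset and 0.042 at the estimated correlation for the 15 genes, and 3.1e-12 and 0.020 for all 18.

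Higher type 2 genes may reflect an immune reaction in the KO nose, which is a hypothesis. The median change of 0.77 over all 18 genes cannot tell about genes picked by chance among the highest changes, as it includes such genes. That of the 15 others, 0.61, lay above the range of -0.15 to 0.16 that holds 95% of 10000 lists matched on mean expression. So these 15 genes were higher in KO by more than genes of like expression. The matched lists draw genes as if they were independent. They cannot exclude a chance difference between few pools in genes that vary together. More ciliated respiratory epithelium in the KO pools would raise the multiciliated genes, whose median was 0.39 (95% bootstrap interval 0.089 to 0.46), and the 15 genes lay 0.22 above it with an interval of -0.085 to 0.65 (all 18 genes 0.38, -0.028 to 0.94), so this stays open; a comparison with the called genes alone, as first written, would favour genes picked for their height. More macrophages in the KO pools stay open too, since several of these genes are macrophage genes and the macrophage list, with a median of 0.65 and all 14 genes positive, was higher by a like amount, the median of the 15 genes differing from it by -0.047 (interval -0.41 to 0.23) and that of all 18 by 0.12 (-0.34 to 0.56). Of the called type 2 genes 0 lay within 10 Mb of Slc12a2, which argues against DNA of another strain kept around the targeted gene as their direct cause, while an effect of such DNA on distant genes, housing and infection of the KO mice were not tested.

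Lower odorant receptors might come from fewer mature neurons in the KO pools, and the test written for it leaves this open. If the neurons alone were fewer, receptors and mature neuron genes would fall alike, but the receptor median lay 0.20 above that of the mature neurons, with a 95% bootstrap interval of 0.074 to 0.34 that neither includes 0 nor lies below it. With a pseudocount of 0.1 the medians were -0.88 and -0.75, so the order depends on how low values are treated, and the receptor sum as a percent of the mature neuron sum, looked at afterwards, was 29.99 ± 2.53 in WT and 32.0 ± 2.14 in KO. Less olfactory tissue in the KO dissections would also lower immature neurons, whose median lay 0.72 above that of the mature neurons (interval 0.56 to 0.93). It would thus not account alone for the fall of the mature neurons. Other olfactory lists went both ways, with sustentacular cells at -0.21 and progenitors at 0.17. Bone (0.58) and fibroblast (0.41) lists were higher, so a smaller share of olfactory tissue stays open as a part of the cause. Bootstrap intervals here resample genes and not libraries. Abundant secretory transcripts would lower matched lists, whose median change was 0.065, and reads shared between near-identical receptor copies would keep the receptor sum, which was 54.7% of WT. With the secretory sum as a covariate only 16 receptors fell. The 80 called without it kept a median change of -1.46 (SE 0.289) where it had been -1.57 (SE 0.287). The gap between all receptors and all genes went from -0.55 to -0.59. This small change in fold gives no support to secretory transcripts as the cause of the receptor fall. Why the calls ended was not settled. The lost residual degree of freedom alone does not account for it. The term for the mixed pools and the female share, added in the same way, gave 168 and 123 receptors that fell.

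A further hypothesis was that the remaining neurons are less active, since Kirrel2 and S100a5, which follow odour activity, had the lowest changes of the 4 mature neuron genes named. Pcp4l1 and Lrrc3b, which also follow it, had log2 changes of -1.21 (95% interval -1.78 to -0.64) and -1.10 (-1.76 to -0.43), a mean of -1.15. Both intervals include the mature neuron median of -0.74, so lower activity of the remaining neurons may or may not add to the fall, and 2 genes cannot decide it.

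Secretory genes split the libraries across genotypes. The KO sum was 137% of the WT sum (190, 277 and 55.1% in the mixed, male and female pools), with overlapping libraries (exact permutation p = 0.3), and 3 against 3 cannot exclude genotype as a part of the cause. The list passed camera at the preset correlation, higher in KO (adjusted p = 7.6e-04), but neither with an estimated correlation (0.45) nor with fry (0.31), so genotype stays open. For depth of the libraries, the 3 libraries of highest sum, KO mixed, KO male and WT female, were neither the 3 deepest nor the 3 shallowest. Most arrangements of 6 libraries would give that outcome, so it decides little. The WT male library, of lowest sum, was the deepest, with an estimated 14220000 fragments. The WT and KO mixed libraries, of near-equal depth, had sums of 43339 and 82354 FPKM. Depth alone thus does not order the sums, and a part played by depth stays open. How much gland each dissection held stays open as a possible explanation.

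Of the 10 ways to split the 6 libraries 3 against 3, genotype gave 126 genes and the highest other split 4. The number of splits reaching the genotype count of called genes was 1, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 in limma, genotype gave 1338 genes and other splits gave more. WT mixed, WT male and KO female against the rest gave 3476, and WT mixed, KO mixed and KO female against the rest gave 1873. Among 85 tested genes within 10 Mb of Slc12a2, 1 was called, Ctxn3, with an odds ratio of 1.40 (one-sided Fisher's exact p = 0.51). The share at an unadjusted p under 0.05 went the other way, 4.7% of these genes against 8.9% of the others. So 1 call is too few to decide whether DNA of another strain kept around the targeted gene adds changed genes there.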
